A study of Danio rerio with 4 samples.

How the data were processed

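The data are 4 Affymetrix arrays of total RNA from whole zebrafish embryos, extracted with Trizol and labelled with biotin, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The deposited table gives 1 intensity per probe set and array on a linear scale. The submitters' processing notes name GCRMA, with no version given. The deposited intensity values have features of another method: the mean after trimming 2% at each end is the same on every array, between 500.15 and 500.16, and the spread grows strongly at low values. Which method made the values stays unknown, and so does whether a background was subtracted. A method that leaves low values noisy gives large fold changes for dim probe sets, so brightness is given beside the differences.

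Of the 15617 probe sets, 115 control probe sets were left out of all tests. Of the other 15502, 10795 carry 1 gene in the platform annotation, 135 carry several and 4572 are not listed with a gene there; these last are unnamed here, and no gene was named from a probe set with several. Symbols were updated through the RefSeq gene table of assembly GRCz12tu, which matched 10711 of the single-gene probe sets by gene identifier and changed 1 symbol. That table was used for names only, and no coordinates are given. In all, 8793 different genes were named. Probe sets of globins and other families of near-identical genes can bind transcripts of several copies, so the copy named is uncertain.

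The log2 of each intensity was taken, and probe sets with a log2 value of at least 5 (an intensity of 32) on at least 2 of the 4 arrays were tested, which removed 1874. No further scaling was applied. Glucose was compared with control by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 without covariates, with Benjamini-Hochberg adjustment over 13628 probe sets and a threshold of 0.10. This leaves 2 residual degrees of freedom per probe set. The number of arrays limits the precision. The biological replicates are separate samples by their labels, and whether they came from separate clutches is not given in the sources used here. Gene lists were tested with camera at a preset correlation of 0.01, on the probe set with the highest mean for each of 8165 genes, over 28 lists with at least 3 tested members, with a threshold of 0.05; camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were run beside it. camera with an estimated correlation rests on the 2 residual degrees of freedom, so its p-values differ from the preset ones for that reason as well. fry passed 0 lists one way and 22 for change in either direction. Annotation used Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.

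The tests, lists, alternatives and naming rule were fixed before the data were examined. The rule named, among probe sets past the threshold with 1 symbol and groups that do not overlap, the 12 largest rises and 12 largest falls, filled by smallest unadjusted p where fewer passed, passing over clone-type names; up to 4 members of smallest unadjusted p per list; and runx1, myb, actb1, eef1a1l1 and rpl13a. As 0 probe sets passed, all 24 names came from the fill. The intensity-trend fit was among the settings fixed beforehand. Reporting single genes from it, applying the naming rule to its calls, and repeating it under the other settings were chosen after the test without trend had given 0 calls. The list members gata1a, klf1, rbp4, fga, fgb and fgg, and the genes of the closing section outside the rule, were chosen after their values were seen.

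The other settings fixed beforehand were leaving out each array in turn, the replicate number as a block, no filter and a stricter filter at a mean log2 of 6, quantile normalization, median centring, an intensity trend, robust eBayes, no moderation, a threshold of 0.05, an unadjusted p under 0.05 with a 1.5-fold difference, the mean of all probe sets of a gene, and the other list tests. A filter at the level of the brightest tag probe set was added after seeing the data.

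The code was tested on simulated arrays with the real means and a spread by level taken from the real arrays, with 200 of 13628 probe sets of mean log2 above 7 changed in each of 10 runs. With the intensity trend, 36.1% of 1.5-fold, 79.3% of 2-fold and 99.1% of 4-fold changes were found, and 11.2% of the calls were false. Without the trend, 0% of 1.5-fold, 0.434% of 2-fold and 66.2% of 4-fold changes were found, and 7.88% of the calls were false. The simulated variance followed mean intensity, as the trend fit assumes, so these rates test the code and are no check of the real calls. The simulated spread was rescaled once after a first version proved too wide. In simulated data with independent genes, camera called 0 unchanged lists and found a list shifted by 0.4 in 10 of 10 runs.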

Results

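Gene expression was measured in whole zebrafish embryos at 36 hours post fertilisation (hpf) on an Affymetrix zebrafish array. Control embryos were compared with embryos raised in 1% glucose in E3, the standard embryo medium, from 12 to 36 hpf. Each of the 2 groups had 2 biological replicates, with 1 array per replicate and 15617 probe sets per array. The median intensity was 171 and 174 on the control arrays and 171 and 175 on the glucose arrays. Between 58.4% and 59.3% of the probe sets lay above 117.7, the highest intensity of the 17 tag probe sets, which have no target in fish. The log2 values of the control pair correlated with r = 0.959 across probe sets, those of the glucose pair with r = 0.964, and those of arrays from different groups with r between 0.955 and 0.961. Probe sets are not independent replicates, so these correlations describe the arrays and carry no test. The ratio of 3' to 5' probe sets, a sign of RNA integrity, was between 2.14 and 2.49 for actin and between 1.45 and 1.78 for Gapdh, with the groups overlapping for both.

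The series is about glucose metabolism and the induction of haematopoietic stem cells, and its only comparison asks which transcripts differ between glucose-treated and control embryos. By camera at its preset correlation, the list of primitive red cell genes lay higher in glucose, with a median difference of 1.41-fold over its 19 measured genes. The liver, gut and yolk list, which holds many apolipoproteins, lay higher by a median of 1.16-fold over 32 genes, and the list of pentose phosphate and nucleotide synthesis genes by 1.23-fold over 19 genes. With an estimated correlation none of the 3 calls held (adjusted p = 0.396 for each, unadjusted p = 0.0498, 0.121 and 0.0495). That version of camera also rests on only 2 residual degrees of freedom. The estimated correlation was above the preset for the erythroid (0.0756) and liver (0.0835) lists. For the pentose phosphate list it was below (-0.000475), yet the unadjusted p rose from 6.85e-05. Where the estimate lay below the preset, a call lost in that version therefore cannot be put down to correlated genes. Where it lay above, correlated genes and the few degrees of freedom may both lower a call and were not told apart. This also holds below for the mitochondrial respiration (0.161) and cell cycle (0.0904) lists. Neural, epidermal and mitochondrial respiration lists lay lower by smaller amounts at the preset correlation, with adjusted p = 0.396, 0.396 and 0.717 with an estimated correlation. No single probe set passed the planned test, limma without an intensity trend, at a Benjamini-Hochberg adjusted p under 0.10. That test gave 0 of 13628 probe sets in either direction, a smallest adjusted p of 0.301, and 613 higher and 539 lower probe sets at an unadjusted p under 0.05, where 681 in all are expected by chance.

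The spread between replicates depended strongly on brightness, with a within-group SD of 1.25 log2 units for probe sets with a mean log2 below 5 and 0.103 for those at 12 and above. A second fit, also fixed beforehand, lets the variance follow intensity (limma with an intensity trend). It placed 176 probe sets higher and 97 lower in glucose at adjusted p under 0.10. In what follows a single gene is said to rise or fall only where it passed this trend test, and its adjusted p without the trend was never below 0.301. The 273 calls fell to 147 without glucose replicate 2 and 214 without glucose replicate 1, and reached 572 without control replicate 1 and 934 without control replicate 2.

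Primitive erythroid genes formed the list with the smallest p. Of its 19 measured members, 18 were higher in glucose, 7 rose in the trend test over all probe sets, and 12 rose when adjusted over the list alone; 12 did not pass over all probe sets. The embryonic beta globin hbbe2 went from an intensity of 4717 ± 569 (SD, n = 2) in controls to 7663 ± 33.0 in glucose, a log2 difference of 0.71 with a standard error of 0.11 (limma with trend, adjusted p = 0.0025). The red cell anion exchanger slc4a1a rose by 0.79 on the log2 scale, from 1544 ± 269 to 2654 ± 127 (adjusted p = 0.00406). The membrane skeleton gene epb41b rose 2.14-fold (adjusted p = 0.00352) and alas2, the first enzyme of haem synthesis in red cells, 1.62-fold (adjusted p = 0.0142). The erythroid master regulator gata1a differed by 0.61 (adjusted p = 0.301) and klf1 by -0.18 (adjusted p = 0.875), and neither passed. For klf1 the difference was -0.47 without glucose replicate 1 and 0.10 without glucose replicate 2. The mean signal of klf1 was not above that of the brightest tag probe set, so a change in this gene could be missed. The list passed camera, which compares its genes with all others, at its preset correlation (adjusted p = 3.14e-08); with an estimated correlation its adjusted p was 0.396.

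**Figure D1:**
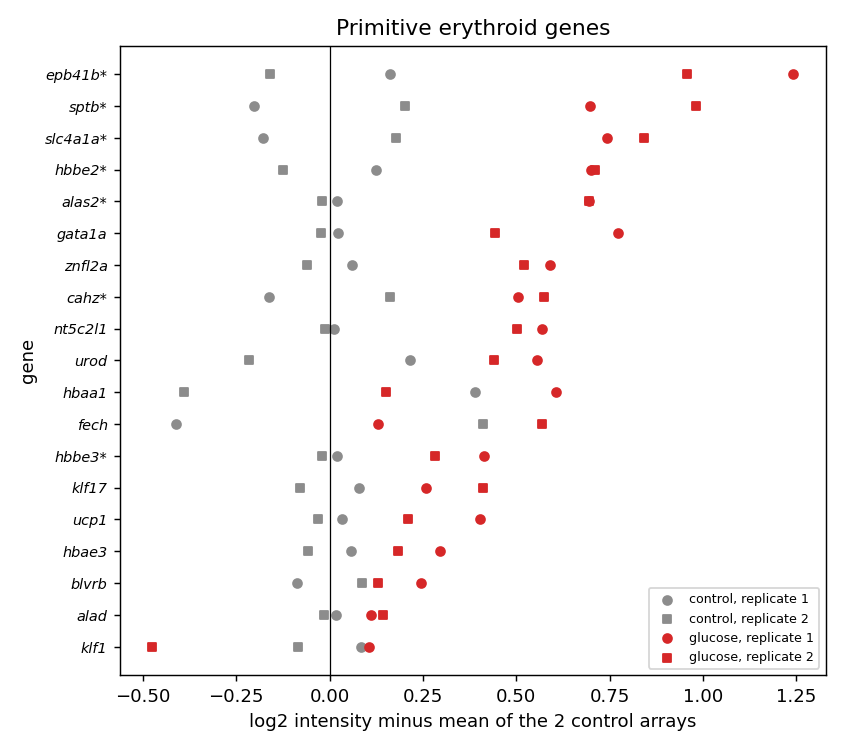
Each row is 1 of the 19 primitive erythroid genes, and each point 1 array, as log2 intensity minus the mean of the 2 control arrays (grey control, red glucose, circles replicate 1, squares replicate 2). Asterisks mark the 7 genes past adjusted p under 0.10 in limma with an intensity trend, and 18 of the 19 genes have a glucose mean above the control mean.

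No shift of the blood stem cell genes as a group passed the test. As the arrays measured whole embryos, this does not exclude a change confined to the stem cells. Of the 13 measured members of the haematopoietic stem and progenitor list, 9 were higher and 4 lower in glucose, none passed the trend test over all probe sets, and 1 higher and 1 lower member passed when adjusted over the list alone. The list had a median difference of 0.14 and a mean of -0.06, which differ in sign; camera placed it higher and it did not pass (adjusted p = 0.633). Its median turned to -0.13 without glucose replicate 2 and to -0.23 with a filter, chosen after seeing the data, that leaves out probe sets below the tag level. The stem cell transcription factor myb had an intensity of 100.5 ± 23.1 (SD, n = 2) in controls and 130.2 ± 16.6 in glucose, a 1.31-fold difference that did not pass (limma without trend, adjusted p = 0.702; with trend, 0.653). The log2 difference of 0.39 was 0.15 without control replicate 1 and 0.62 without control replicate 2. The level of myb is close to that of the brightest tag probe set. For runx1, the other marker of the lineage, the probe set read 9.01 and 3.07 in controls and 62.6 and 7.97 in glucose, below the tag level on all 4 arrays, so no difference was detectable. The member with the smallest trend p, the haematopoietic transcription factor gata2a, differed by 0.53 (adjusted p = 0.107 over all probe sets and 0.0288 adjusted over the list alone).

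Of the 32 measured liver, gut and yolk genes, 25 were higher in glucose; 8 rose in the trend test over all probe sets and 13 when adjusted over the list alone. The lipoprotein gene apoa4b.1 rose 2.41-fold, from 2382 ± 89.9 (SD, n = 2) to 5760.3 ± 505 (limma with trend, adjusted p = 7.34e-06). Another apolipoprotein gene, apoba, rose by 0.87 on the log2 scale and the intestinal fatty acid binding protein gene fabp2 by 0.81 (adjusted p = 5.43e-04 for both). The retinol carrier rbp4, with an intensity of 10577 in controls, differed by -0.03, with a 95% interval from -0.24 to 0.19. The list passed camera at the preset correlation (adjusted p = 2.22e-04); with an estimated correlation its adjusted p was 0.396.

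**Figure D2:**
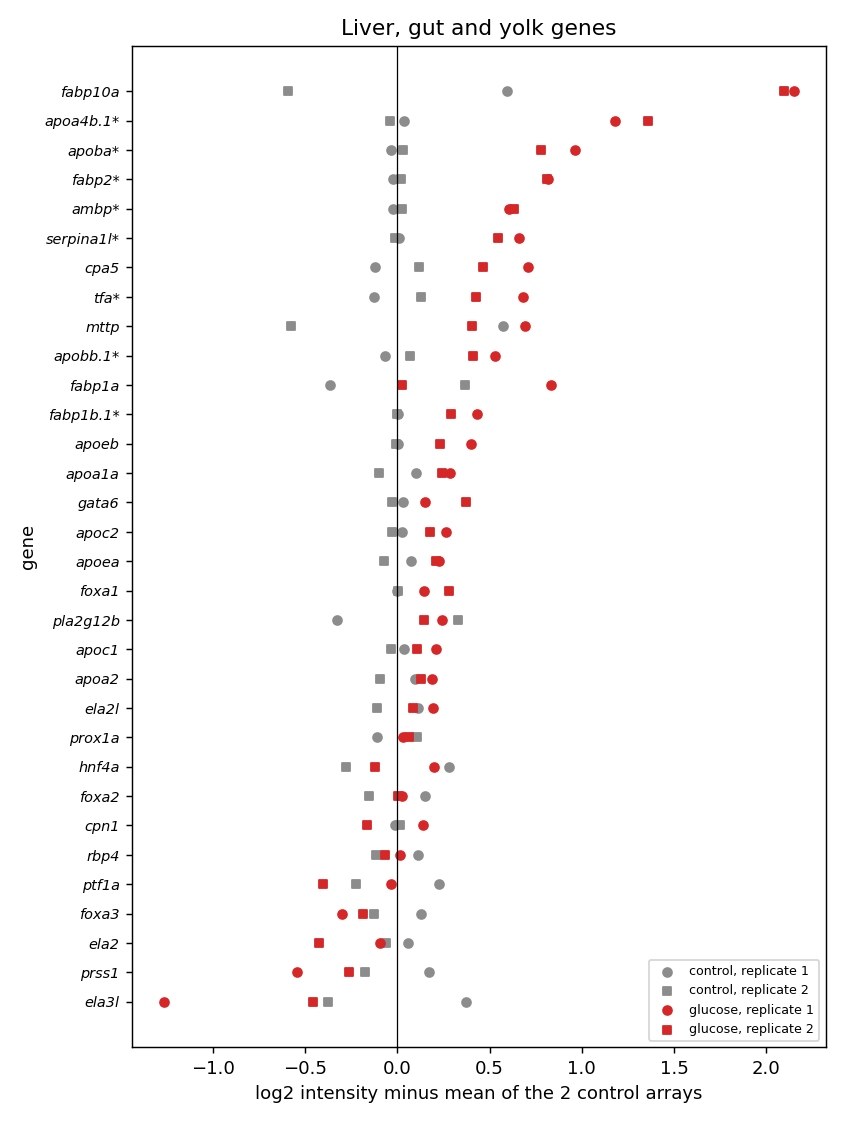
Each row is 1 of the 32 liver, gut and yolk genes, and each point 1 array, as log2 intensity minus the mean of the 2 control arrays (grey control, red glucose, circles replicate 1, squares replicate 2). Asterisks mark the 8 genes past adjusted p under 0.10 in limma with an intensity trend, and 25 genes have a glucose mean above the control mean.

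Of 19 pentose phosphate and nucleotide synthesis genes, 16 were higher in glucose; 5 rose over all probe sets and 9 adjusted over the list alone. They included the purine synthesis enzymes atic (log2 difference 0.59, adjusted p = 0.0108) and paics (0.55, adjusted p = 0.0105), and the transketolase tktb (0.49, adjusted p = 0.0353). The list passed camera at the preset correlation (adjusted p = 6.39e-04) and had an adjusted p of 0.396 with an estimated correlation. The glycolysis list, with 20 of 29 members higher, missed the threshold (adjusted p = 0.0514). It passed in the trend fit (adjusted p = 0.0098) and had an adjusted p of 0.49 with an estimated correlation. Its members pfkfb3, which makes the activator of phosphofructokinase, pklr, a pyruvate kinase, and gpia, a glucose phosphate isomerase, rose by 1.48, 0.71 and 0.51 on the log2 scale. Among 11 gluconeogenesis genes, a list that did not pass (adjusted p = 0.215), 1 rose: fructose bisphosphatase fbp1b, from 1667 ± 14.3 (SD, n = 2) to 3607 ± 91.6 (adjusted p = 5.46e-05). The glucose-induced gene txnipa rose by 0.44 (adjusted p = 0.0738). It belongs to the insulin and growth factor list, in which 14 of 20 were higher (camera adjusted p = 0.0458; adjusted p = 0.396 with an estimated correlation), and whose call was lost in all 4 fits that leave out 1 array.

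Of 21 hypoxia response genes, 16 were higher and 2 rose over all probe sets (4 adjusted over the list alone), the prolyl hydroxylase egln3 2.46-fold (limma with trend, adjusted p = 0.00123) and pfkfb3 again. In the myeloid list 11 of 15 genes were higher and 1 rose, ctss2.1, a cathepsin S gene, which had the largest rise among the genes taken by the naming rule from the trend test (412.6 ± 37.6 to 1561 ± 14.8, SD, n = 2, adjusted p = 7.38e-07). In the heart muscle list 7 of 8 genes were higher and 0 passed over all probe sets. The hypoxia, myeloid and heart lists had the same camera adjusted p of 0.0228, and each had an adjusted p of 0.396 with an estimated correlation. All 3 lost their call without glucose replicate 2, the hypoxia list also without control replicate 1, and the myeloid and heart lists also without control replicate 2. Without control replicate 2 the myeloid median was 0.0166, against 0.22 with all 4 arrays. The myeloid call was also lost with the stricter filter (median 0.0692, adjusted p = 0.0631) and the tag-level filter (adjusted p = 0.0933), and the heart call with no filter (adjusted p = 0.0525). Of 32 cell cycle genes, 24 were higher, with a median of 0.0781 over all 32, and 1 rose, the replication licensing gene mcm2 (0.43, adjusted p = 0.0885). The cell cycle list passed camera (adjusted p = 0.0305; adjusted p = 0.626 with an estimated correlation), lost its call in 3 of the 4 fits that leave out 1 array, and had a median of 0.0202 without control replicate 2 and 0.162 without control replicate 1.

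Genes lower in glucose included 22 of 28 epidermis and ionocyte genes, of which 4 fell over all probe sets and 5 adjusted over the list alone. The secretory cell gene agr2 fell by 0.62 on the log2 scale (limma with trend, adjusted p = 0.0132), the epithelial claudin cldnb by 0.57 (adjusted p = 0.0885), and the fin fold actinodins and1 and and2 by 0.51 and 0.42. Without control replicate 2 the difference for and1 was -0.29. Of 33 neural genes, 22 were lower and 0 passed over all probe sets, with 5 lower adjusted over the list alone; the proneural gene neurod1 differed by -0.49 (adjusted p = 0.177). Both lists had a camera adjusted p of 0.0228 and 0.396 with an estimated correlation. Of 51 genes of mitochondrial respiration and the citric acid cycle, 40 were lower, with a median of -0.0745 over all 51, and the only member past the trend test, the cytochrome oxidase subunit gene cox6b1, rose by 0.56. That list had a camera adjusted p of 0.0317, and 0.717 with an estimated correlation. Its median was -0.112 without control replicate 2 and -0.0588 without control replicate 1. Each of these 3 lists lost its call in 3 of the 4 fits that leave out 1 array.

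Single genes that fell most included fosab, a stress- and growth-induced transcription factor gene. On the probe set with the largest fall of its 4, the intensity went from 435 ± 40.3 (SD, n = 2) to 161 ± 8.16 (limma with trend, adjusted p = 4.62e-04). The brightest, which the naming rule took from the trend test, went from 966 ± 146 to 407 ± 15.7 (adjusted p = 3.46e-04). The log2 differences of the other fosab probe sets were -1.16 and -0.44. The related junbb fell by 0.94 (adjusted p = 0.00299), the transcription factor gene klf2b by 0.94 (adjusted p = 0.01), the calreticulin gene calr3b by 1.17 (adjusted p = 0.00803) and irg1l by 1.02 (adjusted p = 0.0142). In the other direction lay the fibrinogen genes fgb, fga and fgg, which rose by 0.47, 0.56 and 0.43 (adjusted p = 0.0353, 0.0708 and 0.0782); fga differed by 0.35 without control replicate 1. fosab, junbb, irg1l and the fibrinogens belong to the innate immune and acute phase list, which had 3 members rise and 3 fall and did not pass camera (adjusted p = 0.562). The largest rises that the naming rule took from the trend test also held nedd4l, rdh1, mchr1b, usp37, ahsa1a, dpydb and scp2a, with log2 differences from 1.15 for scp2a to 1.69 for nedd4l, and acp5a with 1.18. Control means were below the tag level for nedd4l, rdh1, mchr1b and usp37, and for rdh1 the glucose mean was too. Without control replicate 1 mchr1b differed by 0.86 and usp37 by 0.74. The largest falls also held ncoa7a, spint1b, atp2b4, maco1a, ecrg4a, smarcc1a, hoxc6b and tgm1l4, which fell by between 0.94 (tgm1l4) and 1.52 (ncoa7a). Glucose means were below the tag level for ncoa7a, maco1a and hoxc6b. ncoa7a differed by -0.92 without glucose replicate 1, and atp2b4 by -0.58 without glucose replicate 2. For usp37, ncoa7a, maco1a, spint1b, atp2b4 and pfkfb3 only 1 of the 2 to 4 probe sets passed the trend test. The others differed by -0.10 for ncoa7a, -0.05 for maco1a, 0.51 for pfkfb3, -0.65 and -0.16 for atp2b4, from -0.12 to 0.26 for spint1b and from 0.31 to 0.58 for usp37. Of the 24 genes with the smallest p without the trend, 19 had a mean below the tag level and 5 passed the trend test. Examples below the tag level are got1l1, at 6.34 in controls and 37.1 in glucose, and esr2a, at 41.7 and 8.43, which did not pass either test. Of the probe sets with no gene name, DrAffx.3.1.A1_at fell the most, by 1.72 on the log2 scale (adjusted p = 4.14e-07).

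The remaining lists did not pass camera. Pigment cells had an adjusted p of 0.0514 (0.0241 in the trend fit, and 0.398 with an estimated correlation) and a median difference of 0.20. Median differences were 0.20 for p53 and apoptosis, 0.14 for notochord and cartilage matrix, 0.0507 for the hatching gland, 0.0453 for vascular endothelium, 0.035 for the unfolded protein and heat shock response, 0.0153 for the circadian clock, 0.00727 for lipid and sterol synthesis, 0.00611 for the ribosome, -0.0116 for skeletal muscle, -0.0337 for oxidative stress, -0.0498 for lens crystallins and -0.12 for osmotic stress, with adjusted p between 0.484 and 0.93. These medians depended on single arrays: p53 had 0.0164 without control replicate 2, notochord 0.0281 without control replicate 1, and pigment 0.0926 without glucose replicate 2. Medians and tests differed in sign for the hatching gland, the unfolded protein response, lipid synthesis and the ribosome, which camera placed lower, and for osmotic stress, which it placed higher. The means of the lens list (0.36) and of the oxidative stress list (0.00568) lay above 0, against their medians and tests. The housekeeping genes actb1, eef1a1l1 and rpl13a differed by 0.0121, 0.0328 and 0.0963, with trend standard errors of 0.0844, 0.0839 and 0.0856, and none passed (trend adjusted p = 0.976, 0.932 and 0.737). For rpl13a the difference exceeded its standard error and the groups did not overlap, while the sign for actb1 turned with quantile normalization and with median centring.

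**Figure D3:**
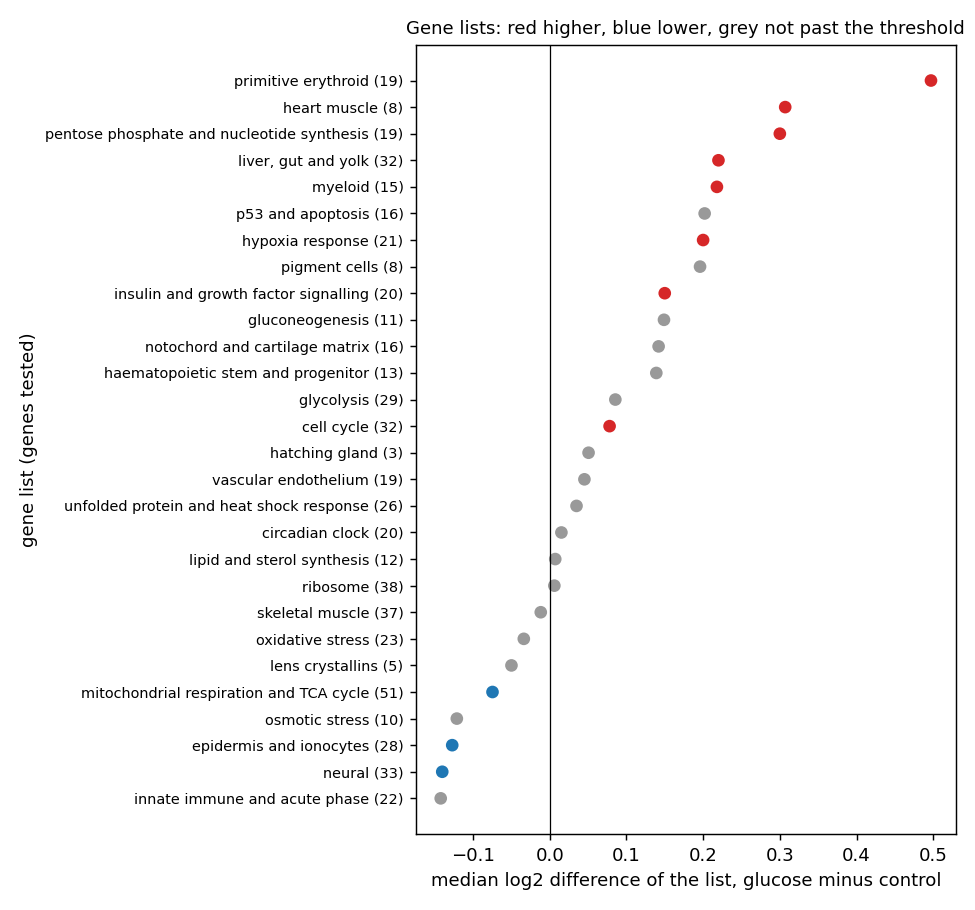
Median log2 difference, glucose minus control, of each of the 28 gene lists, with the number of genes tested in parentheses. Red lists (8) lay higher and blue lists (3) lower by camera with its preset correlation at adjusted p under 0.05, grey lists did not pass, and 0 lists passed with an estimated correlation.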

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

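The repeats of the intensity-trend fit and the filter at the brightest tag probe set were chosen after seeing the data; all other settings were planned. Without a trend, the count of probe sets past the threshold was 0 higher and 0 lower in every leave-one-out fit and in every other planned setting except these: the intensity trend (176 higher, 97 lower) and an unadjusted p under 0.05 with a 1.5-fold difference (369 higher, 372 lower). The filter at the tag level gave 31 higher and 19 lower, with fewer dim probe sets tested. Gene lists past the threshold numbered 11, between 3 and 9 with 1 array left out (9 without control replicate 1, 5 without control replicate 2, 6 without glucose replicate 1, 3 without glucose replicate 2), between 10 and 12 under the other filters, scalings and variance models, and 0 with estimated correlation and 0 with fry. Erythroid, liver and pentose phosphate lists passed in 13 of 15 alternatives each, failing under those list tests; the insulin list failed in 12. The replicate block gave 0 and 0 probe sets and 12 lists. Same-numbered arrays deviated with a correlation of -0.023 across probe sets. No shared deviation was seen, though 1 such value cannot show whether the replicates were paired. The block added the glycolysis and pigment lists and lost the insulin list (camera adjusted p = 0.104). The intensity trend made the same 3 changes, and the stricter and the tag-level filter and the robust fit also added glycolysis. Pigment also passed with no filter and without control replicate 1, and the mitochondrial list failed with quantile normalization (adjusted p = 0.0619) and the robust fit (0.0875).

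For the trend fit, leaving out 1 array gave 88 to 578 higher and 59 to 356 lower; the lone array of a group is then assumed to vary like the other group. Of its 273 calls, 114 were shared without glucose replicate 2 and 262 without control replicate 2. No filter on low values gave 117 higher and 57 lower, adjusted p under 0.05 gave 110 and 51. The mean of all probe sets of a gene gave 135 higher and 62 lower genes, against 135 and 71 different named genes among the 273 calls. The block gave 188 and 113. Other scalings and the robust fit stayed within 1.5 times. With 1 array left out, the medians of all 17 lists that did not pass moved by over 1.5 times, and 8 changed sign, among them the stem cell list (-0.134 to 0.257). Single-gene differences near 0 changed sign when 1 array was left out: eef1a1l1 ran from -0.0036 to 0.0691, actb1 from -0.0117 to 0.0358, rbp4 from -0.139 to 0.0864, cpn1 from -0.162 to 0.137 and klf1 from -0.474 to 0.105. actb1 was also -0.00604 with quantile normalization and -0.00556 with median centring. For these and for the changed counts the cause was not tested. Signal over background limits dim genes. Of the 100 smallest p without trend, 70% had a mean below the tag level. The median of their mean log2 values was 4.9, against 7.81 over all tested probe sets. With the trend the share was 2%, as that fit gives dim probe sets larger standard errors.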

Other observations

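All tests of explanations in this part, and both gene classes in the next paragraph, were chosen after the results were seen.

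Lysosomal genes, a class not among the planned lists, were higher in glucose in 44 of 60 measured members, with a median log2 difference of 0.14. The 7 members past the trend test all rose, among them acp5a, an acid phosphatase (1.18, adjusted p = 1.08e-04), psap, the precursor of the saposins that help break down sphingolipids (0.78, adjusted p = 0.00299), and the cathepsin gene ctsla (0.52, adjusted p = 0.00969). As the list was written after ctss2.1 and acp5a had been seen, a further test leaves out the 7: the other 53 had a median of 0.12 and a camera p of 0.0119. They still hold smpd1, which was among the genes with the smallest p without the trend. It differed by 1.52, at 13.8 in controls and 39.4 in glucose, both below the tag level. The full list had a camera p of 7.84e-05, and p = 0.0662 with an estimated correlation of 0.0139 and 2 residual degrees of freedom. That a rise of the class extends beyond the called genes is a hypothesis only. The other 53 are not free of genes seen beforehand and were tested at the preset correlation only. The gene ctss2.1 also belongs to the myeloid list, where 11 of 15 genes were higher, and these lists were not tested against each other.

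Immediate-early genes, which respond to stimuli within minutes, were lower in 22 of 35 measured members, with a median of -0.20. The 4 past the trend test, fosab, junbb, klf2b and ier2a, all fell, ier2a by 0.91. As this list too was written after such genes had been seen lower, the test leaves out the 4. The other 31 had a median of -0.17 and, at the preset correlation only, a camera p of 0.0272. They still hold klf4, which was among the genes with the smallest p without the trend. It differed by -1.36, at 49.7 in controls and 19.3 in glucose, both below the tag level. That camera p is therefore not free of genes seen beforehand, and whether the class is lower beyond them stays open. The full list had a camera p of 4.41e-04, and p = 0.0555 with an estimated correlation of -0.0209 and 2 residual degrees of freedom. For fosab a fault of a single probe set is argued against: 4 of 4 probe sets lay lower and 3 passed the trend test, while the fourth differed by -0.44 (adjusted p = 0.368). For junbb, klf2b and ier2a, with 1 probe set each, it stays open. A difference in how embryos were handled before lysis could shift such genes, and the class median of -0.202 lies between the bounds set for and against it. Handling was not recorded in the labels used here, so it cannot be told apart from the glucose exposure, which also stays open.

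For the higher erythroid list, a single deviating array is argued against by the medians with 1 array left out, the lowest of which was 0.443. A scaling offset shared by all probe sets is argued against by a median of 0.006 over all named genes. Centring each array left the list median at 0.479. The array medians already lay between 7.78 and 7.84 on the log2 scale, so centring could move the list little and adds no weight. A general advance in developmental stage stays open: skeletal muscle genes had a median of -0.0116 with members going both ways, which decides nothing. More red cells per embryo and more transcript per red cell were not tested against each other.

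For the higher liver, gut and yolk list, a single deviating array is argued against by a lowest median of 0.18 with 1 array left out. A larger share of 1 tissue that raises all list members alike is argued against by their unequal change: over the 24 members above the tag level, the heterogeneity p was 3.63e-25, from trend standard errors with genes taken as independent. The intervals of rbp4 and of the carboxypeptidase gene cpn1 lay below the median of 0.32 over the 17 abundant members, while apoa4b.1 had an interval from 1.04 to 1.51. The list mixes tissues, so a larger share of one of them, such as intestine or yolk layer, stays open, as does a change in lipid handling under glucose.

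The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. The real split, 1 of the 3, gave 273 probe sets with the trend and 11 lists, and the highest of the others 0 probe sets and 0 lists. Each of the others mixes 1 control and 1 glucose array in a pair. A real difference between the groups would then widen the spread and lower the counts, so these counts are no baseline for the real split.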
